A study of Drosophila melanogaster with 12 samples.

How the data were processed

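The series holds 12 RNA libraries of Drosophila melanogaster, made at 6, 12, 18 and 24 h after puparium formation with 3 replicates per time, lettered A, B and C in the labels. Per the labels, each library came from 1000 fluorescent γ neurons of the mushroom body sorted from dissociated brains, and each carried RNA interference against Hr51, a nuclear receptor gene also called unfulfilled. Libraries of a control genotype were not analysed here, so the size of the knockdown could not be measured and times were the only groups that could be compared. The labels do not say whether replicates came from separate dissections, and the p-values therefore measure the spread between these libraries, part of which can be technical.

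Per the labels' protocols, libraries were made with MARS-seq, a 3′-end method developed for small samples. The submitters' processing notes name bcl2fastq, HISAT 0.1.5 and HOMER, without the role of each. How multiply mapped reads, overlapping genes and molecular identifiers were counted is not given in the sources used here. Values of overlapping genes are therefore given as uncertain, and PCR copies cannot be set apart from molecules.

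The deposited table gives, for 17050 genes, a normalised signal per library: per the file headers, reads scaled by the authors to 10000000 mapped reads. Mapped reads per library, computed here as 10000000 over the value of 1 read, numbered 1597241 to 3752666 (median 2345770). In each library 100% of the values above 0 were whole multiples of the value of 1 read, with a tolerance of 0.02 reads, and 1 read was worth 2.66 to 6.26 units. The recovered reads over all genes came to 99.3% to 102% of the mapped reads, and 7521 to 8217 genes per library had at least 1 read. Counting intervals below cover counting error only.

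Gene symbols were matched to the BDGP6 annotation, 12959 directly and 3938 through a synonym, in all 99.1% of the table. The gene coordinates of the table were identical to that annotation for 96.0% of the matched genes. Coordinates are given as the deposited table holds them, counted from 1. The table held 0 genes of the mitochondrial genome.

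The test planned for counts, the quasi-likelihood test of edgeR, was replaced as written beforehand for normalised values: limma 3.58.1 (R 4.3.3) with an intensity trend, on log2(value + 1), with 1 mean per time over all 12 libraries. Fold changes are on this scale, and for genes with low values they can lie below or above the ratio of reads. Genes with a value of at least 50 in at least 3 libraries were tested (6969 genes). That value stood for 8 to 18.8 reads. Comparisons were 6 with 12 h, 12 with 18 h, 18 with 24 h, 6 with 24 h, any change over the 4 times, and the mean of 12 and 18 h less the mean of 6 and 24 h. This last contrast was planned for transient changes, but it also calls genes that change after 6 h and stay changed, and it is therefore named by its times. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The test of single genes, the comparisons, the threshold, the gene lists and the rule for naming genes were fixed before the data were examined. The test of gene lists was also fixed, but the scale it ran on departed from the plan. The filter planned for counts did not apply to normalised values, and the values of the filters used here were chosen after the table was opened.

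Genes were named by a fixed rule: for each comparison, called genes with a log2 change of at least 1, a mean value of at least 200 and no overlap between the libraries of both times (planned for 3 and 3 libraries, applied here to 2 and 2), in order of size of the change. The rule took 12 genes in each direction for 6 with 24 h and 6 in each direction for the other comparisons. Chance gives no overlap between 2 and 2 libraries in 33.3% of cases. Genes known by a CG or CR number were counted and not always named. Hr51, dpr12, DIP-delta, EcR, babo, Sox14, Fas2, Eip75B, Hr39, ftz-f1, br and chinmo were always given, as were up to 4 members of each list with the smallest p. A change against a time with 0 reads is given as a lower bound, computed against 3 reads over the libraries of that time. Against 1 to 3 reads it is given as a ratio with its 95% counting interval.

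In all, 37 gene lists were fixed from general knowledge. They cover ecdysone response, neuronal remodelling, nuclear receptors, growth and TGF-β signalling, cell-surface families, receptors, channels, synapses, neuropeptides, ribosome, proteasome, respiration, glycolysis, cytoskeleton, stress, cell death, autophagy, Kenyon cell identity, neurons and other transmitter types. They also cover glia, hemocytes, fat body, muscle, photoreceptors, dividing cells, cuticle, immunity, mitochondrial RNAs and dosage compensation. The 34 lists with at least 3 members measured were tested with camera of limma, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists, on log2(value + 1). The test was repeated with an estimated correlation. Counts of called members are given over all genes and adjusted over the list alone.

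After the data had been examined, each comparison was also fitted to the 8 libraries of replicates B and C. This choice followed from how the replicate A libraries correlated with the others, and was one of several tried: each of the 3 letters was left out in turn, as was 1 library per time in each of 81 ways. Alternatives planned beforehand were median-ratio and upper-quartile scaling, DESeq2 1.42.0 and limma-voom on the recovered reads, no filter (10258 genes), a stricter filter of 150 (5773 genes), the replicate letter as a block, a 2-fold minimum, leaving out each library in turn, and fitting only the times compared. Alternatives added after seeing the data were edgeR 4.0.16 on the recovered reads, TMM scaling, pseudocounts of 10 and 50, leaving out 1 letter, and all alternatives of the B and C fits.

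No pair of libraries was a duplicate: chi-square per degree of freedom between libraries lay between 15.0 and 110. The script was tested on simulated reads of the 6969 genes with 50 genes changed at each fold, for 6 with 24 h. With 12 libraries it recovered 24% of 2-fold, 56% of 4-fold, 78% of 8-fold and 86% of 16-fold changes, and 2.4% of 125 calls were false. With the 8 libraries of B and C it recovered 12%, 36%, 70% and 84%, and 6.5% of 108 calls were false. Both simulations took the spread of each gene from replicates B and C. The rates for 12 libraries therefore do not cover any wider spread that replicate A adds to the real data.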

Results

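Gene expression was measured in sorted γ neurons, the mushroom body neurons of Drosophila that prune and regrow their axons during metamorphosis. All 12 libraries came from animals with RNA interference against Hr51. They were made at 6, 12, 18 and 24 h after puparium formation, with replicates A, B and C at each time (n = 3), and held 1597241 to 3752666 mapped reads. The series title places the work in a study of the cell-surface proteins Dpr12 and DIP-δ, and the design text names the profiling of γ neurons with perturbed Hr51. Values are reads per 10000000 mapped reads.

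Transcripts of Hr51, the target of the RNA interference, were present in every library, with values from 2661 to 5666. The mean was 4951 ± 765 (SD, n = 3) at 6 h, 4194 ± 738 at 12 h, 4120 ± 1368 at 18 h and 3238 ± 417 at 24 h. From 6 to 24 h the log2 change was −0.61 ± 0.26 (SE), and limma did not call it (adjusted p = 0.331). The steps were −0.24 from 6 to 12 h, −0.07 from 12 to 18 h and −0.30 from 18 to 24 h, none called. The middle step turned to 0.07 without replicate A of 12 h and to 0.22 without replicate C of 18 h. The gene lies on chromosome 2R from 15331325 to 15339384 on the plus strand. Without control libraries these values do not measure the knockdown.

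Over the whole interval, from 6 to 24 h, voltage-gated channels and pan-neuronal markers were among the lists called higher and glycolysis among those called lower in the 12 libraries as labelled. In the same comparison limma called 0 single genes and DESeq2 197 (89 higher, 108 lower). Of the 24 voltage-gated channel genes measured, 7 were higher when adjusted over the list alone, and the list was higher than other genes (camera adjusted p = 5.81e-05, adjusted p = 0.0296 with an estimated correlation). It was the only list of the 34 tested whose call held with an estimated correlation. Of the 11 pan-neuronal markers, 6 were higher adjusted over the list alone (camera adjusted p = 1.13e-05, adjusted p = 0.151 with an estimated correlation). The DIP family, immunoglobulin proteins that bind Dpr partners, had 4 of 7 members higher by the same count (adjusted p = 0.00991, adjusted p = 0.161 with an estimated correlation), and the dpr family 2 of 21 (adjusted p = 0.000879, adjusted p = 0.161 with an estimated correlation). The 12 glycolysis genes had 5 members lower, with a median log2 change of −1.07 (adjusted p = 5.96e-05, adjusted p = 0.333 with an estimated correlation). In all, 15 lists were called with the preset correlation. The others were beat and side genes, axon guidance, ionotropic receptors, synaptic vesicle genes, oxidative phosphorylation, temporal and Kenyon cell transcription factors, Kenyon cell markers and photoreceptor markers, all higher, and proteasome and cell death genes, both lower.

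Among the genes fixed for reporting in the same comparison, DIP-delta had a log2 change of 2.60 ± 1.02 (SE; limma adjusted p = 0.294) and dpr12 of 0.92 ± 0.35 (adjusted p = 0.284). The ecdysone receptor gene EcR had 1.21 ± 0.39 (adjusted p = 0.218), and its transcription factor target Sox14 had −1.24 ± 0.84 (adjusted p = 0.554). The temporal transcription factor gene chinmo had 0.88 ± 0.24 (adjusted p = 0.175). The changes of babo (0.11), Fas2 (0.26), Eip75B (0.18), Hr39 (0.44), ftz-f1 (2.23) and br (−0.11) did not pass either. DIP-delta lies on chromosome 3L from 5424109 to 5442399 on the plus strand, and dpr12 on 2R from 5804712 to 5860831 on the plus strand.

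Limma called 0 of 6969 genes from 6 to 24 h, where 943 had an unadjusted p under 0.05 and chance gives 348. DESeq2 on the recovered reads called 197 (89 higher, 108 lower) and edgeR called 0. Without replicate A of 6 h limma called 676, without replicate A of 12 h 7, and without replicate B or C of 6 h 1 each.

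In the shorter steps the 12 libraries again gave changes in lists and none in single genes by limma. From 6 to 12 h, the step into axon pruning, voltage-gated channels (adjusted p = 0.00551), transcription factors of temporal and Kenyon cell identity (0.00226) and Kenyon cell markers (0.00553) were higher, each with an adjusted p = 0.103 with an estimated correlation. From 12 to 18 h, cytosolic ribosomal proteins and oxidative phosphorylation were higher and glycolysis lower, each at an adjusted p = 0.000307. With an estimated correlation the adjusted p = 0.752 for ribosomal proteins and 0.601 for the other lists. The glycolysis genes took 0.346% of the reads in replicate A of 12 h, against 0.131% and 0.148% in B and C. At 18 h they took 0.127%, 0.112% and 0.149% in A, B and C, so in B and C the shares of both times overlapped. From 18 to 24 h, the step towards regrowth, 9 lists were higher, among them ionotropic receptors (adjusted p = 1.49e-05, adjusted p = 0.0673 with an estimated correlation) and axon guidance genes (adjusted p = 1.08e-05, adjusted p = 0.147 with an estimated correlation). Photoreceptor markers were one of these (adjusted p = 0.0487, adjusted p = 0.0569 with the letter as a block), with a median log2 change of 0.79 and a mean of −0.40. Their call, like that of every other list in this step, ended with an estimated correlation. Cytosolic ribosomal proteins were lower (adjusted p = 0.00173, adjusted p = 0.675 with an estimated correlation). In the comparison of 12 and 18 h with 6 and 24 h, axon guidance genes (adjusted p = 0.0178) and ionotropic receptors (adjusted p = 0.0245) were lower in the middle, both with an adjusted p = 0.549 with an estimated correlation.

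Limma called 0 genes in each of these comparisons. Genes with an unadjusted p under 0.05, of which chance gives 348, numbered 331 from 6 to 12 h, 428 from 12 to 18 h, 484 from 18 to 24 h, 307 for the middle against the ends and 690 for any change over the 4 times. DESeq2 called 3, 5, 23, 2 and 121 genes and edgeR 0, 0, 3, 0 and 0. From 18 to 24 h, median-ratio scaling shifted the median of all genes by 0.12 on the log2 scale and gave 4 calls. Without replicate A of 6 h the counts were 60 from 6 to 12 h, 4 from 18 to 24 h and 506 for any change. Without replicate A of 12 h, 3 genes were called from 18 to 24 h. Leaving out replicate B of 6 h gave 1 call from 6 to 12 h and 1 for any change, replicate B of 12 h 1 call from 12 to 18 h, replicate C of 6 h 1 call from 18 to 24 h, and replicate C of 18 h 1 call for the middle against the ends.

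Replicate A differed from B and C at the early times. At 6 h, EcR was at 3558 in replicate A against 1431 and 1265 in B and C, DIP-delta at 2826 against 39.97 and 275.5, beat-Ic at 7250 against 2.665 and 0, and Kr-h1 at 8.615 against 6675 and 5491. At 12 h the order was the other way, with EcR at 1665 in replicate A against 4464 and 4566, and Kr-h1 at 2628 against 80.31 and 151.1. Across the 6969 genes, which are not independent replicates, the correlation at 6 h was 0.84 between B and C, 0.74 between A and B and 0.71 between A and C. At 24 h these were 0.87, 0.85 and 0.85. The library closest in expression came from another time for 8 of the 12 libraries. Over the 658 genes that changed among B and C, replicate A of 6 h correlated at −0.77 with the mean of B and C at 6 h and at 0.75 with that of 18 h. Replicate A of 12 h correlated at −0.10 with its own time and at 0.84 with 6 h. Replicate A of 24 h correlated best with its own time, at 0.69. Replicate A of 18 h stood at 0.31 with 18 h and 0.27 with 12 h over these genes, but at 0.05 and 0.10 over all 6969 genes and at 0.18 and 0.31 with the mean of each letter removed. All labels were kept as given.

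**Figure D1:**
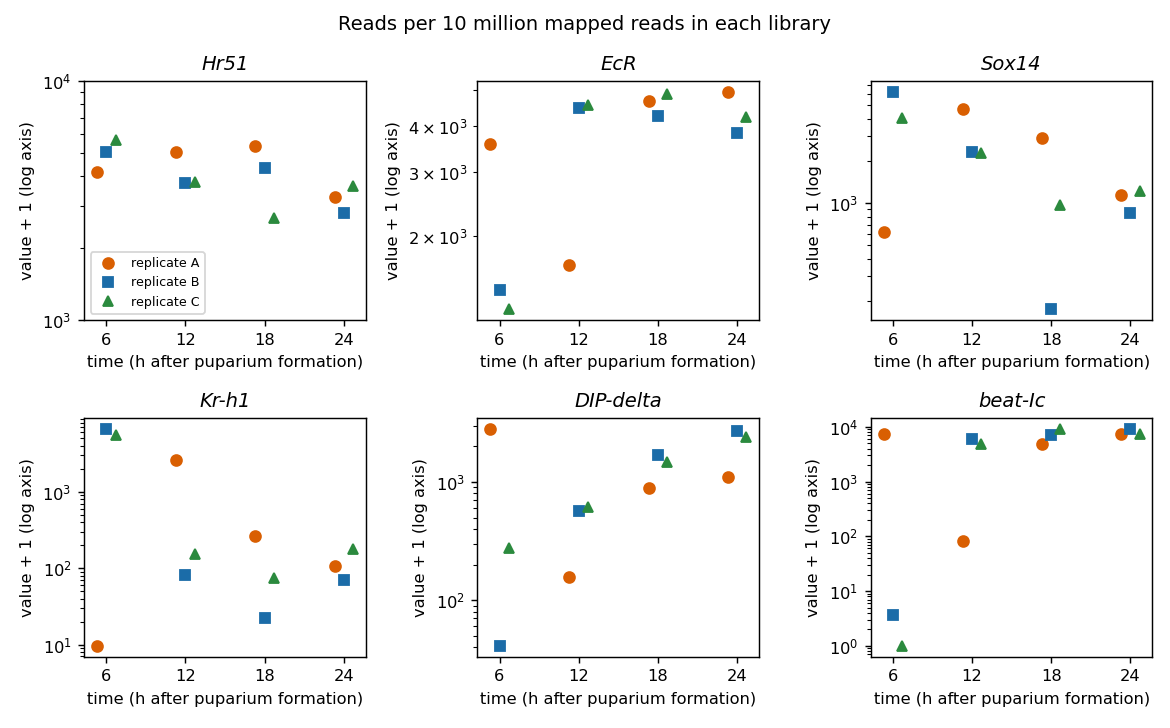
Values + 1 of 6 genes in each of the 12 libraries, in reads per 10000000 mapped reads on log axes, against the time after puparium formation in h; each point is 1 library and its shape and colour give the replicate letter. At 6 h, replicate A stood at 3558 for EcR and 8.615 for Kr-h1, where replicates B and C stood at 1431 and 1265 and at 6675 and 5491.

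**Figure D2:**
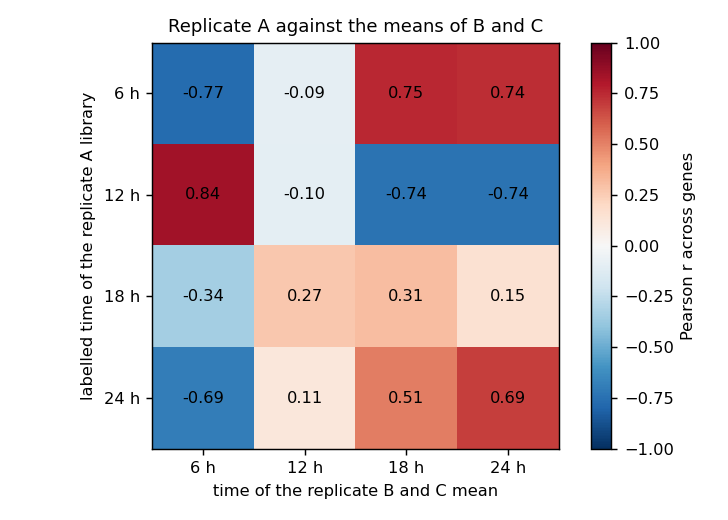
Pearson correlation across 658 genes between each replicate A library (vertical axis, by labelled time in h) and the mean of replicates B and C at each time (horizontal axis, in h), with colour from −1 to 1. The library of 6 h reached 0.75 with 18 h, and that of 12 h reached 0.84 with 6 h.

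Because of this difference, each comparison was also run on the 8 libraries of replicates B and C (n = 2 per time), a choice made after seeing the data. Limma then called 390 genes from 6 to 12 h (230 higher, 160 lower), 25 from 12 to 18 h (2 higher, 23 lower), 9 from 18 to 24 h (7 higher, 2 lower), 702 from 6 to 24 h (369 higher, 333 lower) and 163 in the contrast of 12 and 18 h with 6 and 24 h (79 higher and 84 lower in the middle), which also calls changes that last to 24 h, and 658 with any change. With all 12 libraries each of these counts was 0. The replicate A libraries, which were not in these fits, had the same sign for 275 of the 702 (39.2%) and for 28 of the 390 from 6 to 12 h (7.2%). They had it for 23 of the 25 from 12 to 18 h (92%) and for 6 of the 9 from 18 to 24 h (66.7%). The shares from 6 h rest on replicate A of 6 h, which correlated best with 18 h. The share from 12 to 18 h is no test of that step, because replicate A of 12 h correlated best with 6 h. For CG10713, for example, it stood at 27640 against 5555 and 4582 in B and C of 12 h. The genes below are therefore described for replicates B and C only.

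**Figure D3:**
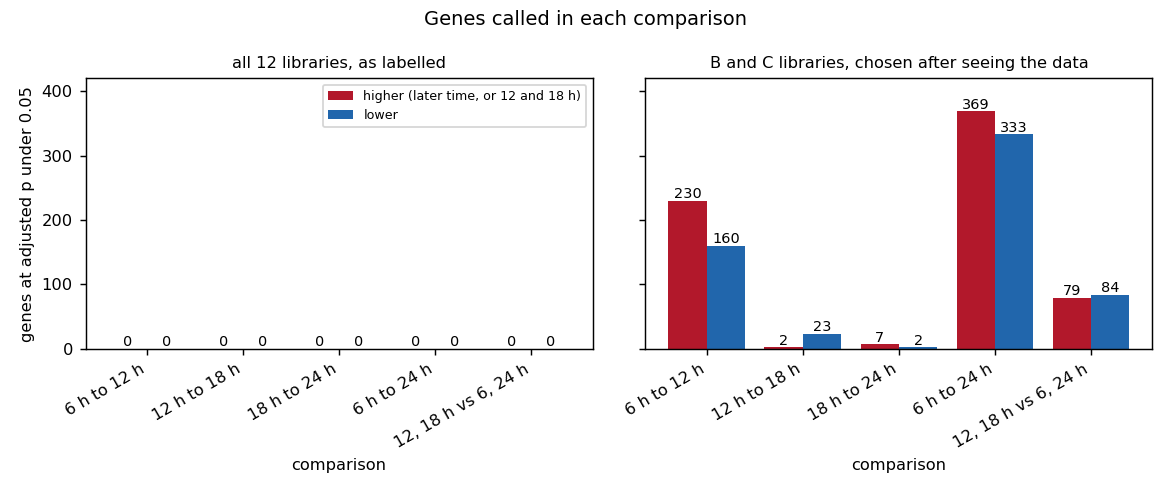
Number of genes at a limma adjusted p under 0.05 in each comparison, higher (red) and lower (blue), with all 12 libraries as labelled (left) and with the 8 libraries of replicates B and C chosen after seeing the data (right). All bars on the left are at 0, and on the right 6 to 24 h has 369 higher and 333 lower genes.

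From 6 to 24 h in replicates B and C, the genes with the largest increase included beat-Ic, a gene of the Beaten path family of immunoglobulin proteins, with 1 read over both libraries at 6 h and 4926 at 24 h, a ratio of 4460 (95% counting interval 799 to 176000). The leucokinin receptor gene Lkr had 0 reads at 6 h and 1076 at 24 h, at least 324-fold higher, and DIP-theta 0 and 431, at least 130-fold higher. The ratio was 513 (91.7 to 20300) for beat-Va and 201 (68.6 to 979) for Hs3st-B, a heparan sulfate sulfotransferase gene. The T-type calcium channel gene Ca-alpha1T rose from 18.3 ± 18.4 (SD, n = 2) to 8465 ± 1115, a log2 change of 9.20 ± 0.53 (SE; limma adjusted p = 1.99e-08). In the other direction, the zinc-finger gene Kr-h1 fell from 6083 ± 838 to 124 ± 76.6 (−5.75 ± 0.76; adjusted p = 8.11e-05). The zinc-finger gene nerfin-1 fell from 1774 ± 59.1 to 31.0 ± 12.6 (−5.85 ± 0.77; adjusted p = 7.88e-05). The anillin gene scra (−5.53 ± 0.57; adjusted p = 7.19e-06) and Osi6 (−7.88 ± 1.40; adjusted p = 0.00122) fell too, and the ratio for the RYamide receptor gene RYa-R was 242 (66.5 to 2000) in favour of 6 h. In replicate A, 6 and 24 h stood at 7250 and 7496 for beat-Ic, 5427 and 7394 for Ca-alpha1T, 8.615 and 107.2 for Kr-h1 and 4.307 and 148 for nerfin-1.

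Of the 24 genes the rule took here, 12 are listed under a CG or CR number. One of them, CG31324, has the current symbol Cipc and fell from 15574 at 6 h to 195 at 24 h (−6.43 ± 0.54, limma adjusted p = 8.81e-07). CG13245 and CG43816 share coordinates inside beat-Ic, with equal reads in 9 of the 12 libraries and at most 2 reads between them, so they count as 1 signal of uncertain origin. CR44844 also lies inside beat-Ic, CG45075 overlaps Kr-h1 and RYa-R overlaps TwdlT. In B and C, RYa-R had 437 reads at 6 h and 2 at 24 h, and TwdlT 411 and 1. The fall of the receptor gene therefore cannot be told from that of TwdlT. Of the 702 genes, 62 overlapped another called gene of the same direction on the same strand and 14 on the opposite strand. The gene beat-Ic lies on chromosome 2L from 16000291 to 16041703 (plus strand), Kr-h1 on 2L from 6082603 to 6096498 (plus strand) and Ca-alpha1T on X from 6104085 to 6192483 (minus strand). The call for Osi7, with 879 reads at 6 h and 0 at 24 h (at least 324-fold lower), ended without replicate C of 6 h. Its log2 change lay between −11.05 and −10.49 over the libraries left out.

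The dpr, DIP and beat and side lists were called higher at 24 h than at 6 h in replicates B and C, though not with an estimated correlation, and most of the members of the dpr and the beat and side lists did not pass. Of 21 dpr genes measured, 7 were higher and 1 lower (9 and 2 adjusted over the list alone), and the list was higher than other genes (camera adjusted p = 0.00385, adjusted p = 0.189 with an estimated correlation). Of 7 DIP genes, 4 were higher and 0 lower (4 and 1 over the list alone; adjusted p = 0.000858, adjusted p = 0.189 with an estimated correlation). Of 22 genes of the beat and side family, 7 were higher and 1 lower (8 and 1 over the list alone; adjusted p = 0.00134, adjusted p = 0.189 with an estimated correlation). DIP-delta rose from 158 ± 167 (SD, n = 2) at 6 h to 590 ± 35.2 at 12 h, 1585 ± 157 at 18 h and 2552 ± 199 at 24 h (log2 change 4.58 ± 0.61, limma adjusted p = 9.46e-05). Its call from 6 to 24 h ended when no filter on low values was used, at the same log2 change. DIP-gamma rose by 5.05 ± 0.28 (adjusted p = 1.64e-08) and dpr6 by 2.93 ± 0.27 (adjusted p = 2.1e-06), while dpr8 fell by 1.06 ± 0.18 (adjusted p = 0.000943). For dpr13 the ratio was 158 (28 to 6290). The change of dpr12 was 1.16 ± 0.41 (adjusted p = 0.0926) and was not called.

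The lists of voltage-gated channels, ionotropic receptors, synaptic vesicle genes and pan-neuronal markers were also called higher, though not with an estimated correlation. Of 24 voltage-gated channel genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.000741, adjusted p = 0.189 with an estimated correlation), among them the sodium channel gene para (2.82 ± 0.26), the channel regulator gene unc79 (3.23 ± 0.27) and the potassium channel gene Sh (1.16 ± 0.17). Of 21 ionotropic and GABA-B receptor genes, 5 were higher and 1 lower (5 and 1 over the list alone; adjusted p = 0.0323, adjusted p = 0.395 with an estimated correlation). The GABA receptor gene Rdl rose by 2.43 ± 0.24, the glutamate-gated chloride channel gene GluClalpha by 1.88 ± 0.20 and nAChRbeta1 by 3.94 ± 0.54, and nAChRalpha1 fell by 1.76 ± 0.28. Of 38 synaptic vesicle and active zone genes, 7 were higher and 1 lower (9 and 1 over the list alone; adjusted p = 0.000858, adjusted p = 0.307 with an estimated correlation). They included Sytbeta (4.85 ± 0.65), Rbp (2.64 ± 0.40) and stnA (2.19 ± 0.26), whose reads cannot be told from those of the overlapping stnB. Of the monoamine and muscarinic receptor genes, 3 of 16 were higher and 3 lower, with DopEcR at 6.03 ± 0.51 and Dop1R2 at −2.59 ± 0.46, whose call ended without the filter (list adjusted p = 0.99). The pan-neuronal markers had 6 of 11 higher and 0 lower (8 and 0 over the list alone; adjusted p = 4.45e-07, adjusted p = 0.189 with an estimated correlation). Among them were the sodium pump subunit gene nrv3 (3.96 ± 0.26) and the RNA-binding protein genes Rbp9 (6.52 ± 0.47) and cpo (1.19 ± 0.16). These markers took 1.40% and 1.14% of the reads of B and C at 6 h and 2.27% and 1.92% at 24 h.

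**Figure D4:**
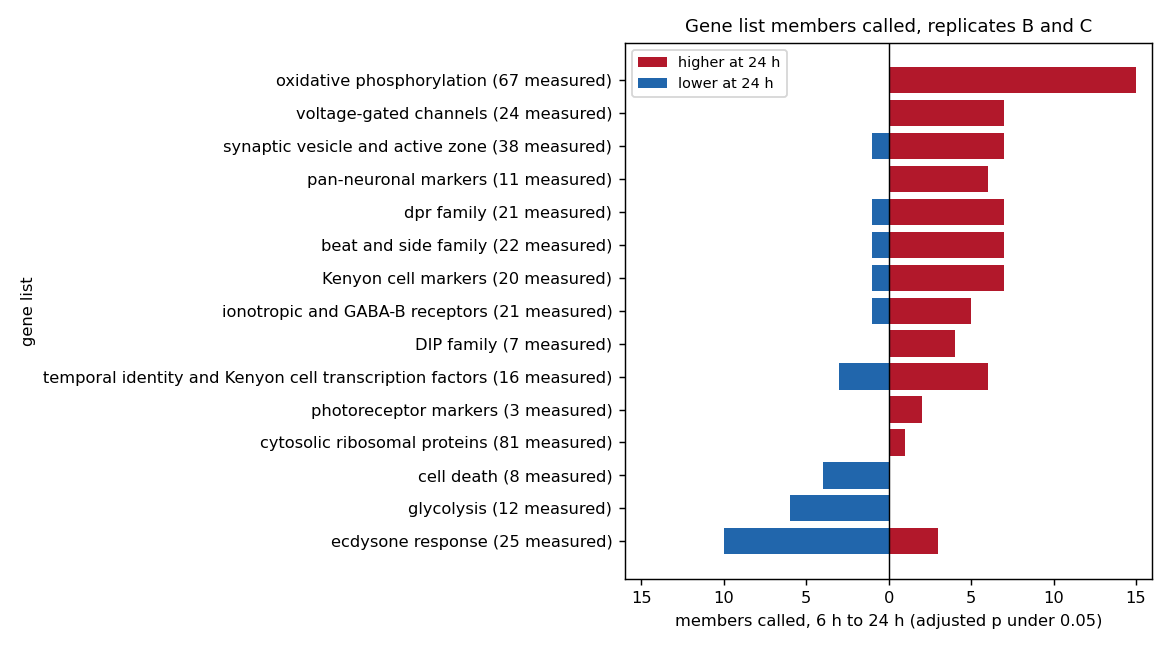
Members of each gene list called higher (red, to the right) or lower (blue, to the left) at 24 h than at 6 h in replicates B and C, for the 15 lists with a camera adjusted p under 0.05 at the preset correlation. Oxidative phosphorylation had 15 members higher and 0 lower, and glycolysis 0 higher and 6 lower.

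Genes of the ecdysone response went both ways. Of 25 measured, 3 were higher and 10 lower at 24 h (3 and 11 adjusted over the list alone; camera adjusted p = 0.0185, adjusted p = 0.433 with an estimated correlation). The transcription factor genes Blimp-1 (4.79 ± 0.26) and Eip93F (2.14 ± 0.19) rose. EcR rose from 1348 ± 118 (SD, n = 2) at 6 h to 4515 ± 71.9 at 12 h and was at 4018 ± 276 at 24 h (1.58 ± 0.22; limma adjusted p = 0.000123). The repressor gene vri fell by 2.78 ± 0.27, and the nuclear receptor genes Hr4 and Hr46 by 2.19 ± 0.36 and 3.39 ± 0.63, calls that ended without the filter, as did those of the next 3 genes. Sox14 (−2.31 ± 0.54; adjusted p = 0.0113) lost its call without any 1 of the 4 libraries of 6 and 24 h (−2.62 to −1.99). The call of br (−1.21 ± 0.33; adjusted p = 0.028) ended without replicate B of 6 h or either library of 24 h (−1.49 to −0.94). That of chinmo (0.83 ± 0.22; adjusted p = 0.0212) ended without replicate C of 6 h or B of 24 h (0.64 to 1.01). Eip75B (−0.03), Hr39 (0.16), babo (−0.35), Fas2 (0.17) and ftz-f1 (adjusted p = 0.477) were not called.

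Of 16 genes listed as transcription factors of temporal and Kenyon cell identity, 6 were higher and 3 lower at 24 h (8 and 3 adjusted over the list alone; camera adjusted p = 0.0269, adjusted p = 0.307 with an estimated correlation). The zinc-finger gene ab rose by 3.59 ± 0.37 and sca, which does not encode a transcription factor, by 2.65 ± 0.20. The RNA-binding protein gene Imp fell by 1.06 ± 0.20, a call that ended without the filter. Of 20 Kenyon cell markers, 7 were higher and 1 lower (8 and 1 over the list alone; adjusted p = 0.0269, adjusted p = 0.333 with an estimated correlation). The neuronal remodelling list had 5 of 32 higher and 3 lower (adjusted p = 0.359), with plum at 1.63 ± 0.27 and the kinase gene Pdk1 at −1.16 ± 0.23. Nuclear receptors had 1 of 13 higher and 3 lower, TGF-β and BMP signalling 1 of 14 higher and 0 lower, and TOR and insulin signalling 1 of 23 higher and 2 lower, with Myc at 1.44 ± 0.21. None of these last lists was called.

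The oxidative phosphorylation and glycolysis lists were called in opposite directions, though not with an estimated correlation, and most oxidative phosphorylation genes were not called. Of 67 oxidative phosphorylation genes, 15 were higher and 0 lower at 24 h (15 and 0 adjusted over the list alone), with a median log2 change of 0.57 (camera adjusted p = 2.73e-06, adjusted p = 0.307 with an estimated correlation). The ATP synthase genes ATPsynC (1.59 ± 0.17) and blw (1.58 ± 0.17) and the cytochrome c gene Cyt-c-p (2.97 ± 0.44) rose. Of 12 glycolysis genes, 6 were lower and 0 higher (7 and 0 over the list alone), with a median of −1.50 (adjusted p = 2.37e-06, adjusted p = 0.189 with an estimated correlation). The enolase gene Eno fell from 13351 ± 1120 (SD, n = 2) at 6 h to 4472 ± 140 at 12 h and was at 4317 ± 128 at 24 h, and Gapdh2 fell by 1.92 ± 0.27. Cytosolic ribosomal proteins had 1 of 81 members higher and 0 lower, RpL10, whose call ended without replicate B of 6 h or either library of 24 h (0.70 to 1.55). The list was called (camera adjusted p = 0.0429), but not with an estimated correlation (adjusted p = 0.812) or with median-ratio scaling (adjusted p = 0.103). None of 70 mitochondrial ribosomal protein genes or 32 proteasome genes was called.

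The cell death list was called lower at 24 h, though not with an estimated correlation. Of its genes, 4 of 8 were lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.00538, adjusted p = 0.189 with an estimated correlation). The 4 calls held genes of opposite known roles, the caspase gene Dcp-1 (−1.53 ± 0.31) and the caspase inhibitor gene Diap1 (−0.96 ± 0.20). The call of Dcp-1 ended without replicate C of 6 h (−1.84 to −1.22 over the libraries left out) and that of Diap1 without replicate B of 24 h (−1.15 to −0.78). The other 2 calls, of the caspase genes Dronc (−1.83 ± 0.51) and Drice (−1.91 ± 0.56), ended without any 1 of the 4 libraries of 6 and 24 h, and that of Drice also without either library of 12 h (−2.06 to −1.61 and −2.49 to −1.32). Heat shock and early response genes had 5 of 21 lower and 0 higher, with Hsp67Bc at −1.84 ± 0.20 and Hsp23 at −1.25 ± 0.19 (list adjusted p = 0.525). Axon guidance and adhesion genes had 11 of 62 higher and 8 lower (adjusted p = 0.802), with Dscam2 at 2.64 ± 0.27, sli at 2.32 ± 0.30 and Fas1 at −1.96 ± 0.21. Cytoskeleton genes had 4 of 42 higher and 4 lower (adjusted p = 0.525), with Act5C at 1.53 ± 0.16 and the microtubule-severing enzyme gene spas at −2.56 ± 0.44, whose call ended without the filter. Autophagy genes had 2 of 21 lower and 0 higher (adjusted p = 0.525), Atg3 and Atg7, and both calls ended without any 1 of the 4 libraries of 6 and 24 h (−1.41 to −1.06 and −2.52 to −1.73).

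Most markers of other cell types were not called from 6 to 24 h in replicates B and C, but neither were most of all genes (702 of 6969 called). These counts therefore do not show how pure the sort was. Of 5 glia markers measured, 1 was lower, nrv2, a call that ended without either library of 6 h or replicate C of 24 h (−1.85 to −0.74), and the list was not called (camera adjusted p = 0.363). Glia markers took 0.0603% and 0.0502% of the reads of B and C at 6 h and 0.0334% and 0.0233% at 24 h. Of 4 muscle markers 1 was higher (bt, 2.49 ± 0.30), and of 7 fat body markers 0. Of 3 hemocyte markers 1 was higher, Pxn, a call that ended without replicate B of 6 h or either library of 24 h (3.51 to 6.33). In the list of transmitter genes 1 of 5 was higher, VAChT, a call that ended without either library of 6 h or replicate B of 24 h (0.88 to 1.43). VAChT and ChAT, both in that list, serve acetylcholine, the transmitter of Kenyon cells themselves. The rise of VAChT therefore cannot tell Kenyon cells from other neurons that use acetylcholine. That list took 0.0404% and 0.0517% of the reads of B and C at 6 h and 0.103% and 0.0732% at 24 h. In B and C, muscle markers took 0.0471% and 0.0422% of the reads at 6 h and 0.0913% and 0.0749% at 24 h, and photoreceptor markers 0.0453% and 0.0419% and then 0.108% and 0.12%. Shares of reads were not tested. Of 12 dividing-cell genes 1 was lower (scra), of 6 cuticle genes 1 was lower (TwdlT, a call that ended without either library of 6 h or replicate C of 24 h, −9.64 to −7.58), and of 4 neuropeptide genes 0 were called. Photoreceptor markers had 2 of 3 higher (adjusted p = 0.0126, adjusted p = 0.189 with an estimated correlation), norpA (1.58 ± 0.23) and Galphaq (1.22 ± 0.20), signalling genes also used outside the eye. No antimicrobial peptide gene passed the filter, no mitochondrially encoded gene was in the table, and of the dosage compensation RNAs roX1 rose by 1.62 ± 0.20 (limma adjusted p = 4.87e-05).

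Of the 702 calls, 617 were at least 2-fold. Without replicate C of 24 h the count from 6 to 24 h was 403, and without replicate B of 24 h 419. In such fits the lone library of a time is assumed to vary like those of the other times.

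Of the 702 genes called from 6 to 24 h in replicates B and C, 320 (45.6%) were also called from 6 to 12 h, an overlap that is partly built in because both comparisons use the same libraries of 6 h. From 6 to 12 h, beat-Ic had a ratio of 2980 (95% counting interval 534 to 118000), Lkr was at least 97.2-fold higher, and Ca-alpha1T rose by 6.75 ± 0.53 (SE). Kr-h1 fell by 5.77 ± 0.76 (limma adjusted p = 0.000193), and the allatostatin receptor gene AstA-R1 had a ratio of 445 (123 to 3680) in favour of 6 h. Blimp-1 rose by 4.71 ± 0.26, Eip93F by 2.22 ± 0.19, EcR by 1.75 ± 0.22 (adjusted p = 0.000114) and DIP-gamma by 3.40 ± 0.28. Hr4 fell by 3.37 ± 0.36. DIP-kappa, listed as CG31814, fell by 4.07 ± 0.73 (adjusted p = 0.00257), a call that ended without replicate C of 6 h (−4.45 to −3.69 over the libraries left out). DIP-delta (2.47 ± 0.61; adjusted p = 0.026) lost its call without any 1 library except replicate C of 6 h (1.10 to 3.85). The calls of Osi6 and nvy ended without either library of 6 h or replicate C of 12 h, with log2 changes of −6.78 to −4.95 and −6.50 to −3.78. The calls of AstA-R1, CG31814, DIP-delta, Osi6 and nvy also ended without the filter.

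Among the lists called in this step, glycolysis had 5 of 12 members lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 4.15e-07, adjusted p = 0.34 with an estimated correlation), with Eno at −1.58 ± 0.19, Pgk at −1.72 ± 0.29 and Hex-A at −1.97 ± 0.33, whose call ended without the filter. Cytosolic ribosomal proteins had 2 of 81 higher (2 over the list alone, adjusted p = 9.35e-06, adjusted p = 0.676 with an estimated correlation). Oxidative phosphorylation had 7 of 67 higher (14 over the list alone; adjusted p = 2.6e-05, adjusted p = 0.412 with an estimated correlation). The list of transcription factors of temporal and Kenyon cell identity had 6 of 16 members higher (7 over the list alone; adjusted p = 0.000404, adjusted p = 0.34 with an estimated correlation). Voltage-gated channels had 4 of 24 higher (5 over the list alone; adjusted p = 0.0168, adjusted p = 0.34 with an estimated correlation), and pan-neuronal markers 4 of 11 (4 over the list alone; adjusted p = 0.000985, adjusted p = 0.412 with an estimated correlation). The ecdysone response had 3 of 25 higher and 6 lower (4 and 10 over the list alone; adjusted p = 0.0168, adjusted p = 0.458 with an estimated correlation). Photoreceptor markers had 2 of 3 higher and 0 lower (2 and 0 over the list alone; adjusted p = 0.0168, adjusted p = 0.34 with an estimated correlation). The cell death list was lower with 0 of 8 members called (0 higher and 1 lower over the list alone; adjusted p = 0.0275, adjusted p = 0.34 with an estimated correlation). These were all 9 lists called. Of the lists called from 6 to 24 h, dpr (adjusted p = 0.0528), DIP (0.108), beat and side (0.158), Kenyon cell markers (0.188), synaptic vesicle genes (0.371) and ionotropic receptors (0.569) were not called by 12 h. The dpr list was called with the letter as a block (adjusted p = 0.0419) and with median-ratio scaling (0.0323). The difference between the steps was not tested.

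Of the 390 genes called from 6 to 12 h, 59% were higher. This share was 46.6% with median-ratio and 47.4% with TMM scaling, which shifted the median of all genes by −0.13 on the log2 scale. The count was 157 without replicate C of 12 h, 236 without replicate B of 12 h, 250 without the filter and 158 with only the libraries of 6 and 12 h.

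Between 12 and 18 h in replicates B and C, limma called 25 genes, 23 of them lower at 18 h. The bicarbonate transporter gene Ndae1 (−2.20 ± 0.31; limma adjusted p = 0.00854) and the unc-13 family gene unc-13-4A (−2.20 ± 0.32; adjusted p = 0.0103) fell, and both calls ended without either library of 12 h (−2.69 to −1.71 and −2.59 to −1.80). CG10713 fell by 2.30 ± 0.24 (adjusted p = 0.000473) and kept its call without each library in turn. The adaptor gene Crk (−4.10 ± 0.82), the adenylyl cyclase gene Ac13E (−3.31 ± 0.60) and br (−1.66 ± 0.33; adjusted p = 0.0446) were lower at 18 h, and eIF-5A, a translation factor gene, was at −2.20 ± 0.42. Each of these calls ended without at least 6 of the 8 libraries taken singly, with log2 changes of −5.75 to −2.44, −4.15 to −2.48, −1.89 to −1.44 and −2.48 to −1.92. The 25 calls came to 1 without replicate C of 12 h, 3 without replicate B of 12 h, 13 without either library of 24 h and 5 with only the libraries of 12 and 18 h. They came to 129 with DESeq2 (39 higher, 90 lower), 54 with edgeR, 49 with voom, 44 with the stricter filter, 45 with the replicate block, and 51 and 61 with pseudocounts of 10 and 50. Both without the filter and with only the libraries of the times compared, every call named above except that of CG10713 ended. Of 34 lists 6 were called, among them the ecdysone response, lower (0 members higher and 1 lower, 0 and 3 adjusted over the list alone; camera adjusted p = 0.0016, adjusted p = 0.535 with an estimated correlation), and oxidative phosphorylation, higher with 0 members called (adjusted p = 0.000686, adjusted p = 0.535 with an estimated correlation).

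Between 18 and 24 h, nrv3 (1.68 ± 0.26; limma adjusted p = 0.0226), the calcium-binding protein gene Nca (1.66 ± 0.25; adjusted p = 0.0226), Hr4 (2.11 ± 0.36; adjusted p = 0.0341) and the casein kinase gene CkIIalpha (2.80 ± 0.51; adjusted p = 0.0498) were higher in replicates B and C, and scra (−3.09 ± 0.57; adjusted p = 0.0499) was lower. Nca shares its reads with the overlapping CG7646. Each of these calls ended without at least 4 of the 8 libraries taken singly, with log2 changes of 1.66 to 1.71 for nrv3, 1.42 to 1.90 for Nca, 1.65 to 2.57 for Hr4, 2.28 to 3.32 for CkIIalpha and −3.56 to −2.61 for scra. The 9 calls came to 0 without replicate C of 18 h or either library of 24 h, 3 without either library of 12 h, 4 without either of 6 h, 14 without replicate B of 18 h and 0 with only the libraries of 18 and 24 h. They came to 104 with DESeq2 (86 higher, 18 lower), 55 with voom, 25 with edgeR, 15 with median-ratio scaling, 18 without the filter, 18 with the replicate block and 22 with a pseudocount of 50. Each call named above also ended without the filter and with only the libraries of the times compared. Of 34 lists 10 were called. Ionotropic receptors were higher with 0 members called (6 higher adjusted over the list alone; camera adjusted p = 2.3e-08, adjusted p = 0.235 with an estimated correlation), and cytosolic ribosomal proteins were lower with 0 called (2 higher and 1 lower over the list alone; adjusted p = 3.35e-11, adjusted p = 0.428 with an estimated correlation).

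The contrast of 12 and 18 h with 6 and 24 h in replicates B and C called changes that lasted to 24 h along with some that receded. Of its 163 genes, 126 were also called from 6 to 24 h in the same direction, 70 had both middle means beyond those of both ends, and 17 were at 24 h less than midway from their level at 6 h to that of the middle. Values of the contrast were 3.14 ± 0.53 for Teh1, a sodium channel subunit gene (limma adjusted p = 0.00404), 2.01 ± 0.19 for Blimp-1, 0.97 ± 0.15 for EcR (adjusted p = 0.00266), −3.62 ± 0.54 for Kr-h1, 0.96 for betaTub56D and 0.73 for Act5C, all of them also called from 6 to 24 h. Teh1, for example, was at 37.8, 1095, 1834 and 1111 at the 4 times, and Kr-h1 at 6083, 116, 47.6 and 124. Hr4 (−2.74 ± 0.25) and the octopamine receptor gene Octbeta1R (−2.96 ± 0.47; adjusted p = 0.00254) were also called from 6 to 24 h, Octbeta1R not without any 1 of the 4 libraries of those times (−2.77 to −2.16). DIP-kappa, listed as CG31814 (−3.14 ± 0.51; adjusted p = 0.00329), was not called from 6 to 24 h. Without the filter the calls of Teh1, Kr-h1 and CG31814 in this contrast ended. Glycolysis had 2 of 12 members lower (7 adjusted over the list alone; camera adjusted p = 3.43e-07, adjusted p = 0.493 with an estimated correlation), and cytosolic ribosomal proteins 2 of 81 higher (2 over the list alone; adjusted p = 3.46e-14, adjusted p = 0.596 with an estimated correlation). In all 7 lists were called. Of the 163 genes 48.5% were higher, against 31% with median-ratio, 36.8% with upper-quartile and 33.3% with TMM scaling, which shifted the median of all genes by up to −0.12. The count was 325 with DESeq2, 78 at a 2-fold minimum, 57 without replicate C of 12 h, 100 and 91 without B and C of 18 h, and 75 and 82 without B and C of 24 h.

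Over the 4 times, the 658 genes with any change in replicates B and C had their highest mean at 6 h in 283 cases (43%), at 12 h in 62 (9.4%), at 18 h in 116 (17.6%) and at 24 h in 197 (29.9%). The lowest mean was at 6 h for 313. Without replicate C of 6 h the count was 420, and without the filter 343.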

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

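Of the settings below, the values of the filters, edgeR, TMM scaling, the pseudocounts, the omission of a letter and every B and C fit were chosen after seeing the data. With 12 libraries, limma's 0 calls became, with DESeq2, 3 from 6 to 12 h, 5 from 12 to 18 h, 23 from 18 to 24 h, 197 from 6 to 24 h, 2 for the middle against the ends (12 and 18 h with 6 and 24 h) and 121 for any change. From 18 to 24 h, median-ratio, upper-quartile and TMM scaling each gave 4, edgeR and a pseudocount of 50 each 3, and the libraries of those times alone 1. Leaving out 1 library gave 0 to 60, 0 to 1, 0 to 4, 0 to 676, 0 to 1 and 0 to 506 in the same order. Leaving out replicate A gave 390, 25, 9, 702, 163 and 658, and leaving out B or C gave 0. Hr51 was between −0.38 and −0.14 from 6 to 12 h over the libraries left out, −0.29 and 0.22 from 12 to 18 h, −0.58 and −0.08 from 18 to 24 h, and −0.73 and −0.51 from 6 to 24 h. From 12 to 18 h it turned to 0.15 without replicate C. The causes were not tested.

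With replicates B and C, all 12 libraries gave 0 for each of the 6 counts. From 6 to 12 h, no filter gave 250, the libraries of those times alone 158 and leaving out 1 library 157 to 349. From 12 to 18 h, DESeq2 gave 129, voom 49, edgeR 54, the stricter filter 44, pseudocounts of 10 and 50 51 and 61, those times alone 5 and single omissions 1 to 22. From 18 to 24 h, median-ratio scaling gave 15, DESeq2 104, voom 55, edgeR 25, no filter 18, a pseudocount of 50 22, those times alone 0 and single omissions 0 to 14. Single omissions gave 403 to 686 from 6 to 24 h, 57 to 157 for the middle against the ends and 420 to 588 for any change. For the middle against the ends, DESeq2 gave 325 and a 2-fold minimum 78. No filter gave 343 for any change. Hr51 from 6 to 24 h was at −0.74 (adjusted p = 0.0779).

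The replicate letters do not pair the libraries: deviations of libraries with the same letter correlated at −0.34 to 0.07, and 2 of 12 libraries correlated best with their own letter. With the letter as a block, limma called 0 in all 12-library comparisons. With B and C the block gave 45 from 12 to 18 h and 18 from 18 to 24 h, and changed no other count by over 1.5 times. With an estimated correlation, called lists fell from 3, 3, 10, 15 and 2 to 0, 0, 0, 1 and 0 with 12 libraries, and from 9, 6, 10, 15 and 7 to 0 each with B and C. From 6 to 12 h with B and C, the dpr list went from adjusted p = 0.0528 to 0.0419 with the block and 0.0323 with median-ratio scaling. Median-ratio scaling raised the lists called for the middle against the ends from 2 to 4.

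Of 161 named calls with B and C, 104 held without each library in turn and 57 ended without at least 1. With no filter 64 of them ended, with only the times compared 33, with voom 9 and with all 12 libraries 161. At the filter a value stood for 8 to 18.8 reads, which limits genes near it.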

Other observations

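The tests of replicate A by exchanged labels, and all 3 tests of its libraries of 6 and 12 h alone, were chosen after the result was seen, as were the B and C fits and the counts over omitted libraries. The other splits of the libraries, and the tests of offset and depth over all 4 replicate A libraries, were chosen before their results.

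The replicate A libraries of 6 and 12 h did not sit with B and C of their labelled times. That of 24 h did, and that of 18 h varied with the setting. Before the correlations below, each gene was centred on a mean over the 4 times. An offset shared by the replicate A libraries is argued against as the whole cause: with each letter's mean removed, 3 of the 4 libraries still correlated best with another time, and both those of 6 and 12 h (2 of 2) did. Depth is argued against for the libraries of 6 and 12 h, since after thinning all libraries to the same number of reads 2 of 2 stayed best at another time, while over all 4 libraries the count, 2, does not decide. An exchange of the labels of 6 and 12 h with each other is argued against by the correlation of replicate A of 6 h with 12 h, −0.09 against 0.75 with 18 h. An exchange among more of the replicate A libraries may be a candidate explanation and cannot be told apart from other differences between these libraries: it needs at least 3 of the 4 at another time and 4 different best times, which held over all 6969 genes (3 of 4) and with letter means removed (3 of 4) but not over the 658 genes (2 of 4), and turned on replicate A of 18 h alone, at 0.10 with 12 h against 0.05 with 18 h, 0.31 against 0.18, and 0.27 against 0.31. Replicate B of 18 h, set against C over all genes, also correlated best with another time, so such small differences do not decide, and no biological explanation was tested.

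The comparison of B and C was selected, and its counts carry that selection. Of the 81 ways of leaving out 1 library per time, leaving out every replicate A library gave the most genes for any change, 658, against at most 615 for another choice and a median of 0. When the best of 3 omissions was taken for each of 33 splits of the 12 libraries (99 fits), the real labels gave 658 and another split up to 640. The median of the other splits was 0, and 1 of the 33, the real one, reached 658. Over the 24 assignments of the replicate A libraries to the times, 10 gave more genes than the labels and the highest, 1049, came from the best times over all 6969 genes, whereas for B and for C all 24 gave 0. The planned fit without replicate A of 6 h, which holds the same 8 libraries and so is no independent test, also called 589 of the 702 genes from 6 to 24 h (83.9%), 472 of the 658 with any change (71.7%) and 59 of the 390 from 6 to 12 h (15.1%).

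Where the labels gave 0 genes, every other split of the libraries gives as many by construction, so the splits say nothing about chance there. For each step and for 6 with 24 h these were 10 of 10 splits of 3 and 3, also too few for a share under 0.05; the real count was 0 and the highest other was 549 for 6 with 12 h and 0 for the rest. For any change, 100 of 100 drawn splits of the 12 libraries gave at least the real 0, with up to 577, and for 12 and 18 h with 6 and 24 h 100 of 100 did, with up to 422. Splits that call many more genes than the labels point to a structure of the samples. For any change among B and C, 1 of 100 splits, the real one, reached 658, and the highest other gave 465. Those 8 libraries were chosen after seeing how they correlated, so splits within them cannot exclude chance.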
